A study of Mus musculus with 16 samples.

How the data were processed

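RNA of adipose tissue from female mice was hybridised to 16 one-colour (Cy3) Agilent 4x44K whole mouse genome arrays, 4 for each of 4 groups: WAT control, WAT GR knockout, BAT control and BAT GR knockout. Total RNA (500 ng) was extracted with a column kit, per the labels. Each of 4 slides held 1 array of each group, and each group had its own array position on every slide, so position and group cannot be separated. Per the file headers, the authors extracted the images with Agilent Feature Extraction 12.0.0.7. Its processed signal is an intensity, background-subtracted and detrended within the array, with no scaling between arrays, per the file headers. The deposited median signal and median background columns are raw intensity values. The deposited flag columns are of another kind: each is 0 or 1 for a spot. The deposited value table is an intensity on a linear scale: for all 16 arrays and all 41174 probes it equals the mean processed signal of a probe's spots within a relative tolerance of 1e-04, so it is not scaled between arrays. Its column medians were 134, 103, 112 and 138 in WAT controls 1 to 4, 94.5, 94.4, 145 and 73.0 in WAT knockouts, 76.6, 67.0, 68.5 and 63.7 in BAT controls, and 51.5, 48.8, 63.7 and 59.3 in BAT knockouts.

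Each array had 45018 spots, of which 1639 were controls and 43379 were not; 40929 probes were spotted once and 245 were spotted 10 times. Spots marked as non-uniform or as population outliers were dropped and repeated spots averaged. The log2 of the processed signal minus the 75th percentile of the array (298 to 1035 over the arrays) was the level of a probe. A probe was kept when it was well above background on at least 3 of the 4 arrays of at least 1 group; 66.7% to 83.6% of probes were well above background on an array. Probes were named by matching their transcript accession, without its version, to a RefSeq gene annotation (GRCm38), which named 28223 of 41174 probes, for 19096 symbols; 12951 stayed unnamed and were tested as probes. Where several probes named 1 gene, the one with the highest mean level was used. This left 16677 named genes and 8430 unnamed probes, 25107 in all. Positions on the genome were not used. The arrays of WAT knockout 1 and 2 differed by no more than spot noise (ratio of SDs 0.970, against at least 1.79 in the other pairs) and were averaged to 1 sample, so that n = 3 for that group; this was decided after the arrays were seen.

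Comparisons were WAT knockout against control, BAT knockout against control, their difference (the genotype by depot interaction), and BAT against WAT in controls and in knockouts. A linear model with 1 mean per group over the 15 samples (11 residual degrees of freedom, prior degrees of freedom 2.65) was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with the package data.table, version 1.17.8. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and probes within a comparison and a threshold of 0.05. Gene lists were tested with camera at a correlation of 0.01, again with the correlation estimated from the data, and adjusted over the 29 lists; estimated correlations were between 0.0592 and 0.883, and with them 0 lists were called in any of the 5 comparisons (smallest adjusted p 0.247 in WAT, 0.282 in BAT, 0.302 in the interaction, 0.0965 and 0.181 between depots in controls and knockouts), against 24, 9, 20, 19 and 21 at 0.01. For Nr3c1 an exact permutation test of the group means was run as well. The 29 lists, the comparisons, the filter, the threshold, the test and the rule for naming genes were fixed before the data were examined; 3 further lists (intestinal epithelium, pancreatic acinar cells, lymph node stroma) were added later and describe sample content only. The intestinal list is reported with the WAT samples; pancreatic and lymph node stroma lists are reported among the other observations.

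Genes were named by this rule: Nr3c1; the 8 largest rises and 8 largest falls among named genes past the threshold whose groups did not overlap; up to 3 members of each list past the threshold by smallest adjusted p (2 between depots); and 5 each way for the interaction. In the WAT knockout comparison F10 and Lancl3 passed but lay outside this rule. They were added so that all named genes past the threshold are given. Genes that did not pass were named after their values were seen. The level of a list in a sample is the median, over its measured members, of the log2 deviation from the gene's mean over the samples. A lower-bound fold uses the level at which spots of the group become well above background. The procedure was tested on simulated data with known changes of log2 1, 2 and 3. It called 29.9%, 71.6% and 84.8% of them in the WAT design and 19.4%, 62.7% and 92.4% in the BAT design. Between depots it called 28.4%, 82.1% and 89.4%. Of unchanged genes it called 0.0362%, 0.0201% and 0.0483%. The simulated noise was independent between genes, with the same SD in all groups. It held no correlation between genes, no unlike samples and no slide effect, so these rates need not hold for the real data.

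Alternatives were quantile or median scaling, normexp background correction, other filters, the value table, all probes singly, slide or replicate number as a block, a fit of the compared groups alone, moderation with trend, array weights, a stricter threshold, pairing of depots by replicate number and each sample left out. Normexp (offset 50) was to use a mean signal column; the files have none, so it used the median signal and median background. Whether samples of the same number in WAT and BAT come from 1 mouse is not stated, so they were not paired. The Cre line, the white depot and the deleted part of Nr3c1 are not given in the labels, and no genome sequence was at hand to place the probes.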

Results

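RNA from white adipose tissue (WAT) and brown adipose tissue (BAT) of female mice was measured on 16 one-colour whole-genome expression arrays, 4 for each of WAT control, WAT GR knockout, BAT control and BAT GR knockout. The labels describe the knockout as an adipose-specific knockout of the glucocorticoid receptor (GR, encoded by Nr3c1). The arrays of WAT knockout 1 and 2 differed by no more than the noise between spots: the SD of their log2 difference was 0.0825 against 0.0851 from spot noise, and 0 of 7114 bright probes differed over 2-fold. In the other 119 pairs of arrays the lowest such SD was 0.171. These 2 arrays were therefore averaged and counted as 1 sample, WAT knockout 1-2, which leaves 3 WAT knockout samples and 15 samples in all. The 75th percentile of the signal was 853 ± 130 (SD) in WAT controls, 664 ± 119 in WAT knockouts, 534 ± 26.1 in BAT controls and 400.4 ± 106 in BAT knockouts (4 arrays each), and 66.7% to 83.6% of the probes of an array were well above background. The number of arrays limits the precision of every value. Levels of genes are log2 signal minus the 75th percentile of the array, given as mean ± SD. The level of a list in a sample is the median, over its genes, of the log2 deviation from the gene's mean over the samples. Changes are log2 ± SE, knockout minus control or BAT minus WAT. A fold against a group that was well above background on no array is a lower bound, computed against the level needed for a spot to be well above background, and is written "at least".

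The first question was how far the receptor's own transcript was lower in the knockout samples of each depot. In BAT, Nr3c1 was 2.49 ± 0.16 in controls (n = 4) and 1.45 ± 0.21 in knockouts (n = 4), so knockouts held 48.8% of the control level, a difference of -1.03 ± 0.18 on the log2 scale. In WAT, Nr3c1 was 2.19 ± 0.28 in controls (n = 4) and 1.53 ± 0.15 in knockouts (n = 3), which is 63.4% of the control level and a difference of -0.66 ± 0.19. Every knockout sample lay below every control of its depot. The exact permutation test (two-sided) gave p = 0.0286 in each depot, the smallest that these group sizes allow. The limma test over all genes did not pass (adjusted p = 0.0814 in BAT and 0.210 in WAT). Within the 4 slides the Nr3c1 difference was -1.10, -1.22, -0.87 and -0.94 in BAT and -0.57, -0.95, -0.42 and -0.58 in WAT, where slides 2 and 4 hold the 2 arrays counted as knockout 1-2. With slide as a block it was -1.03 in BAT (adjusted p = 0.188) and -0.61 in WAT (adjusted p = 0.295). Of the other 3 Nr3c1 probes, the differences were -1.89, -0.40 and -1.08 in BAT (exact permutation p = 0.0286, 0.314 and 0.0286) and 0.24, -0.19 and -0.38 in WAT (exact permutation p = 0.886, 0.200 and 0.200). The probe at -1.89 was well above background on 1 of the 4 BAT knockout arrays, so the size of its difference rests on values near background. Which part of the gene was deleted, and where the probes lie relative to it, is not given by the labels. These percentages are therefore levels of the probed sequence and not of functional receptor. They are also levels in tissue RNA, and the cell content of the WAT samples differed, so they do not measure the loss within adipocytes.

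The BAT comparison asked which transcripts differ between knockout and control brown fat. Hsd11b1, whose enzyme regenerates active glucocorticoid from its inactive form, fell in BAT knockouts from 5.50 ± 0.20 to 3.30 ± 0.26 (4.59-fold, n = 4 in each group, limma adjusted p = 0.0342). Msmo1, a sterol methyl oxidase of cholesterol synthesis, fell from 2.90 ± 0.05 to 1.74 ± 0.22 (2.24-fold, adjusted p = 0.0487). The nuclear receptor gene Nr4a2 rose from 1.35 ± 0.31 to 2.98 ± 0.24 (1.63 ± 0.23, adjusted p = 0.0487). Magel2, an imprinted gene expressed from the paternal allele, rose from -4.23 ± 0.29 to -1.30 ± 0.43 (7.63-fold, adjusted p = 0.0487). For each of these 4 genes all 4 knockout samples lay beyond all 4 controls, and the genotype by depot interaction did not pass (Hsd11b1 -1.22, adjusted p = 0.378; Msmo1 -0.88, 0.359; Nr4a2 1.5, 0.347; Magel2 1.92, 0.373). In WAT, Hsd11b1 differed by -0.98 ± 0.29 (adjusted p = 0.212).

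**Figure D1:**
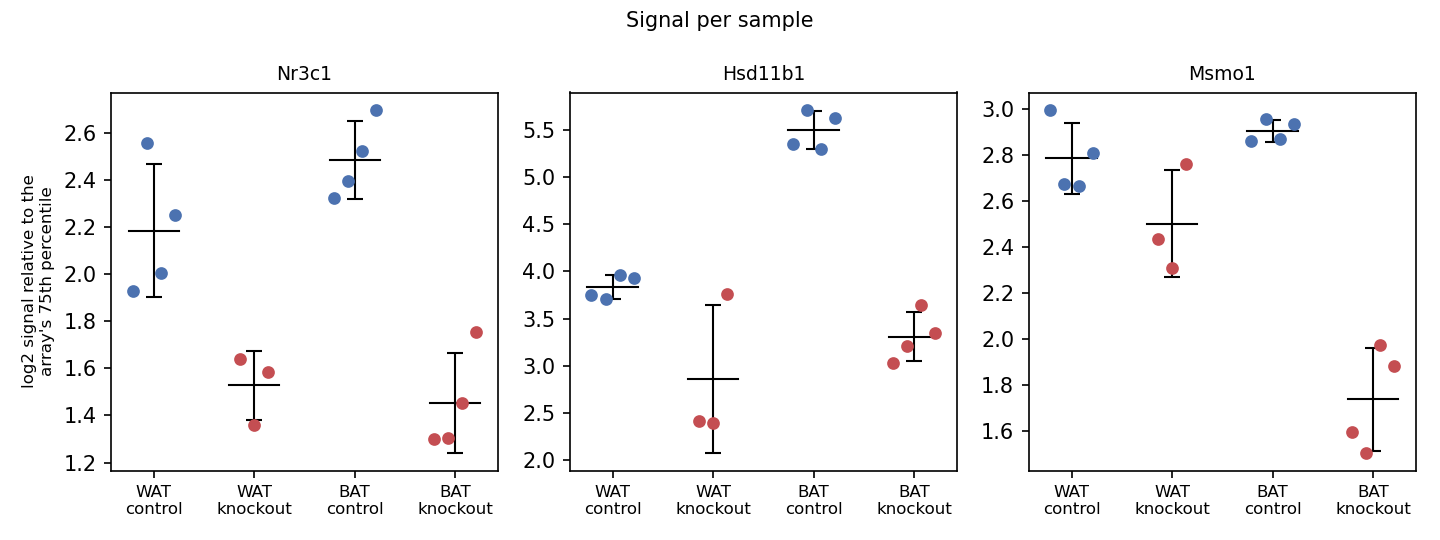
Levels of Nr3c1, Hsd11b1 and Msmo1 (log2 signal minus the array's 75th percentile) in each sample of the 4 groups, with the mean and SD as bars. In BAT, knockouts lie below controls for all 3 genes: the Hsd11b1 mean is 5.50 in controls and 3.30 in knockouts.

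The median of all genes was 0.10 higher in BAT knockouts than in controls, and list medians in BAT are not taken relative to it unless stated. The cholesterol synthesis list was lower in BAT knockouts: its median change was -0.72, or -0.82 relative to the median of all genes, and 20 of its 23 members were lower (camera adjusted p = 2.83e-12, or adjusted p = 0.282 with an estimated correlation). Msmo1 fell over all genes and the other 22 members did not pass; adjusted over the list alone 10 fell. The next members by adjusted p were Sqle at -1.75 ± 0.32 (adjusted p = 0.0991) and Cyp51 at -1.48 ± 0.32 (adjusted p = 0.155). The list's level was 0.59 ± 0.13 in BAT controls and -0.19 ± 0.19 in BAT knockouts, with no overlap between samples. Within the 4 slides its median change relative to all genes was -1.18, -0.82, -0.68 and -0.52. With slide as a block its median change, not relative to all genes, was -0.72 (camera adjusted p = 3.2e-12). The genotype by depot interaction of this list did not pass (median -0.30, adjusted p = 0.100), and the list was called lower in WAT knockouts (median -0.36, or -0.60 relative to all genes, adjusted p = 5.17e-06, or adjusted p = 0.247 with an estimated correlation). Its level was -0.73 and -0.66 in WAT knockouts 1-2 and 3 but 0.12 in WAT knockout 4, against -0.15 to 0.21 in WAT controls. Within slide 3 the WAT change relative to all genes was 0.05.

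Genes known to be induced by glucocorticoid showed no common direction in BAT: 21 of 33 listed genes were higher and 12 lower in knockouts (median 0.18, camera adjusted p = 0.593, adjusted p = 0.945 with an estimated correlation). None of the 33 passed over all genes in the limma test, and adjusted over the list alone 2 rose and 2 fell. Mt2, a metallothionein gene, differed by -1.74 in BAT (adjusted p = 0.177) and by -1.70 in WAT (adjusted p = 0.177). Ddit4 differed by 1.57 (adjusted p = 0.182), Tsc22d3 by 0.80 (adjusted p = 0.251) and Fkbp5 by 1.03 (adjusted p = 0.545) in BAT. Ddit4, Tsc22d3, Fkbp5 and Mt2 were chosen after their values were seen. Lower in BAT knockouts were the lists of lipogenesis (median -0.40, adjusted p = 0.00282), fatty acid oxidation and TCA cycle (-0.27, adjusted p = 0.00204) and antioxidant enzymes (-0.20, adjusted p = 0.00439), each at adjusted p = 0.945 with an estimated correlation. Within the 4 slides the medians, here relative to all genes, were -1.10, -0.22, -0.19 and -0.35 for lipogenesis and -0.81, -0.45, -0.13 and -0.05 for fatty acid oxidation. They were -0.99, -0.32, -0.12 and -0.19 for antioxidant enzymes, so on this scale all were largest on slide 1, which held BAT knockout 1. List levels, not relative to all genes, were 0.43, 0.47, 0.50 and 0.35 for lipogenesis in BAT knockouts 1 to 4 (controls 0.78 to 0.95). They were 0.97, 1.05, 1.24 and 1.45 for fatty acid oxidation (controls 1.49 to 1.66). For antioxidant enzymes they were -0.07, 0.15, 0.24 and 0.18 (controls 0.32 to 0.45), so every knockout lay below every control in each of these lists. Higher in BAT knockouts were endothelial markers (median 0.55, adjusted p = 0.00282) and ribosomal proteins (0.32, adjusted p = 0.00380), both at adjusted p = 0.945 with an estimated correlation. The endothelial level was 1.13 and 0.83 in BAT knockouts 1 and 2 and 0.20 and 0.11 in knockouts 3 and 4, against -0.09 to 0.08 in controls, and the ribosomal level was 0.31, 0.14, -0.22 and -0.23, against -0.39 to -0.27. Most of both changes was thus in knockouts 1 and 2, whose arrays had the lowest 75th percentiles (298 and 320.2, against 497 and 486). Interferon response genes (0.46, adjusted p = 0.00282) and immediate early genes (0.43, adjusted p = 0.0350), among which Nr4a2 rose, were higher too, both at adjusted p = 0.883 with an estimated correlation. None of the members of these 7 lists passed over all genes apart from Nr4a2, and adjusted over the list alone 2 immediate early genes rose and 0 members of the other 6 lists passed. Thermogenic genes had a median of 0.02 (camera adjusted p = 0.272) with a mean of -0.16, and Ucp1 differed by 0.17 (adjusted p = 0.950). The adipocyte list had a median of 0.00 and a mean of -0.09 (adjusted p = 0.315), and oxidative phosphorylation a median of 0.08 and a mean of -0.02 (adjusted p = 0.584).

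Skeletal muscle markers were higher in BAT knockouts (median 2.03, 23 of 23 members higher, camera adjusted p = 9.77e-10, adjusted p = 0.883 with an estimated correlation), and 0 of 23 passed over all genes or adjusted over the list alone. Their level was 2.36, 2.71, 1.91 and -1.24 in BAT controls 1 to 4 and 1.95, 5.26, 4.91 and 2.44 in BAT knockouts 1 to 4, so muscle RNA content differed between samples of both groups. Without BAT control 4 the median change of the muscle list was 1.14 (adjusted p = 9.7e-06), and without BAT knockout 1 that of the interferon list was 0.30 (adjusted p = 0.0133). The immediate early list was no longer called without BAT control 1 (0.30, adjusted p = 0.0787), BAT control 4 (0.33, adjusted p = 0.107), BAT knockout 2 (0.30, adjusted p = 0.0710) or BAT knockout 4 (0.42, adjusted p = 0.292), nor with slide as a block (0.43, adjusted p = 0.0569).

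In BAT 4 of 25107 genes and unnamed probes passed the limma test at an adjusted p of 0.05, and 3300 had an unadjusted p under 0.05, against 1255 by chance. The groups did not overlap for 18.0% of the genes, against 2.86% by chance. Without BAT knockouts 1 and 2, which leaves fewer samples, 997 had an unadjusted p under 0.05 in limma. Over bright probes the SD of the log2 difference from a BAT control array was 0.535 to 0.688 for BAT knockouts 1 and 2. For BAT knockouts 3 and 4 it was 0.262 to 0.323, so the knockout samples were not equally far from the controls. With slide as a block the adjusted p of Hsd11b1 was 0.0945, of Magel2 0.116, of Msmo1 0.176 and of Nr4a2 0.188. Within the 4 slides Hsd11b1 differed by -2.69, -2.10, -1.71 and -2.28 and Msmo1 by -1.36, -1.37, -0.88 and -1.05. Nr4a2 differed by 1.41, 2.18, 1.36 and 1.57, and Magel2 by 2.35, 2.80, 3.32 and 3.26. The count of 4 was 0 without BAT control 1, 3 or 4, 0 without BAT knockout 1, 2 or 3, 1 without BAT control 2 and 79 without BAT knockout 4. It was 0 with normexp background correction and 12 in a fit of BAT samples alone, in which all 4 genes passed. With the muscle marker level as a covariate it was 0 too (2217 at an unadjusted p under 0.05 in limma), with Hsd11b1 at -2.27, Msmo1 at -1.19, Nr4a2 at 1.66 and Magel2 at 2.59, each at adjusted p = 0.279. Leaving out a WAT sample, which enters through the shared estimate of spread, gave 5 without control 1, 0 without control 2 or 4, 2 without control 3, 1 without knockout 1-2 or 3, and 84 without knockout 4.

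The WAT comparison asked which transcripts differ between knockout and control white fat. Zfp949, a zinc finger gene, rose from -1.16 ± 0.15 to 0.78 ± 0.33 (3.85-fold, n = 4 and 3, limma adjusted p = 0.00150). Prg4, which encodes lubricin, fell from 1.57 ± 0.84 to -1.64 ± 0.60 (9.28-fold, adjusted p = 0.00525). Padi4, a peptidylarginine deiminase gene, fell 6.55-fold (-2.71 ± 0.33, adjusted p = 0.00513). Its other probes on the array differed by -2.53 and by only -0.48. Slc6a2, the noradrenaline transporter gene, fell at least 1.86-fold (adjusted p = 0.000525). Alox15, a lipoxygenase gene, fell 10.5-fold (-3.39 ± 0.48, adjusted p = 0.0164). The mast cell protease gene Cma1 fell 9.82-fold (-3.30 ± 0.49, adjusted p = 0.0249), and the mesothelial gene Wt1 fell 7.02-fold (-2.81 ± 0.45, adjusted p = 0.0407). The noncoding imprinted RNA Rian (15.6-fold, -3.96 ± 0.54, adjusted p = 0.0121), Spock3 (at least 2.15-fold, adjusted p = 0.00470), the coagulation factor gene F10 (5.47-fold, -2.45 ± 0.37, adjusted p = 0.0249) and Lancl3 (at least 1.16-fold, adjusted p = 0.0249) fell as well. Vmn1r76 rose (at least 1.75-fold, adjusted p = 0.0287). Slc6a2, Spock3 and Lancl3 were well above background on the 4 WAT control arrays alone and Vmn1r76 on 3 of the 4 WAT knockout arrays alone, so the tests of these 4 genes rest partly on values at background. For these 12 genes all 3 knockout samples lay beyond all 4 controls. In BAT none of the 12 passed the limma test, and of their interactions with depot only that of Slc6a2 passed. A fall of Slc6a2, Spock3 or Lancl3 in BAT could not have been seen, since they were well above background on no BAT array. Nor could a fall of Wt1, which was well above background on no BAT control array. Zfp949 differed by 0.76 in BAT (adjusted p = 0.181, interaction -1.19, adjusted p = 0.347). The mast cell genes Cpa3 and Mcpt4, with Cma1 in the list of granulocyte and mast cell markers, differed by -3.03 (adjusted p = 0.0629) and -2.99 (adjusted p = 0.0617) and did not pass. Lower mast cell genes or Wt1 in tissue RNA may come from fewer such cells in the samples, which was not tested.

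The WAT knockout samples were unlike each other in cell content. The adipocyte marker level was 0.12, 0.49, -0.20 and -0.23 in WAT controls 1 to 4, and -2.17, -1.51 and 0.77 in WAT knockouts 1-2, 3 and 4. B cell markers were 0.53, 0.03, 3.62 and 2.97 in the controls and 5.01, 4.66 and -1.22 in the knockouts. T and NK cell markers were -0.16, -0.65, 2.65 and 2.09 against 3.87, 3.66 and -0.82. The 2 knockout samples with the lowest adipocyte levels thus had the highest lymphocyte levels, and knockout 4 had the reverse. WAT controls 1 and 4 also held intestinal transcripts, at list levels of 6.38 and 5.03 against -1.35 and 0.60 in controls 2 and 3 and -1.25, -0.06 and -0.62 in the knockouts.

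**Figure D2:**
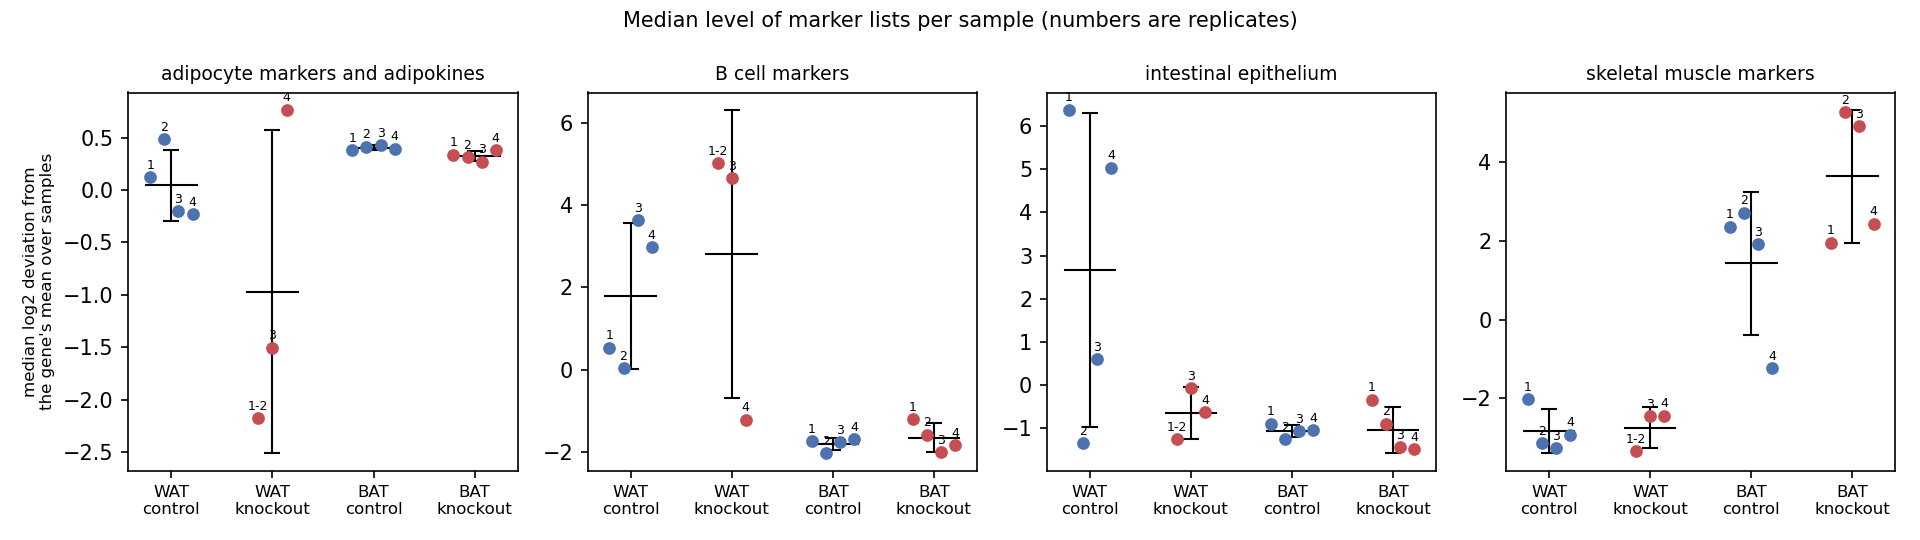
Median level of the members of the adipocyte, B cell, intestinal and skeletal muscle lists (median log2 deviation from each gene's mean over the samples) in each sample, numbered by replicate, with the group mean and SD. Adipocyte markers are at -2.17 and -1.51 in WAT knockouts 1-2 and 3 and at 0.77 in WAT knockout 4, and B cell markers are at 5.01, 4.66 and -1.22 in the same samples.

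Scaling left the median of all genes 0.24 higher in WAT knockouts than in controls, so list medians for all samples in WAT are given relative to all genes. The lists of lipogenesis (relative median -1.33, 27 of 27 members lower, camera adjusted p = 1.06e-13) and adipocyte markers (-1.25, 25 of 25 lower, adjusted p = 1.03e-10) were lower in WAT knockouts, both at adjusted p = 0.247 with an estimated correlation. Fatty acid oxidation and TCA cycle (-0.95, adjusted p = 6.6e-13, with an estimated correlation adjusted p = 0.247) and oxidative phosphorylation (-0.67, 40 of 40 members lower, adjusted p = 1.03e-10, with an estimated correlation adjusted p = 0.300) were lower as well. Extracellular matrix and fibroblast genes (-1.38, adjusted p = 4.2e-15), lipolysis (-1.09, adjusted p = 2.46e-08), glucocorticoid-induced genes (-0.64, adjusted p = 0.000125), macrophage markers (-0.57, adjusted p = 2.12e-07) and inflammatory mediators (-0.69, adjusted p = 7.34e-05) were lower, each at adjusted p = 0.247 with an estimated correlation. No member of these 9 lists passed over all genes. Adjusted over the list alone 19 matrix genes, 7 macrophage genes and 5 inflammatory genes fell and 0 in the other 6 lists. The level of glucocorticoid-induced genes was -0.99 and -0.88 in WAT knockouts 1-2 and 3 but 0.16 in WAT knockout 4, against -0.36 to -0.15 in WAT controls. Within slide 3, which held WAT knockout 4, the change of this list relative to all genes was -0.03. Mesothelial markers (-2.12, adjusted p = 4.41e-05, with an estimated correlation adjusted p = 0.247) were lower, Wt1 among them fell over all genes, and adjusted over the list alone 8 fell and 1 rose. The mesothelial level was -0.26, 0.94 and 1.05 in WAT knockouts 1-2, 3 and 4, against 0.96 to 1.91 in WAT controls. Within the 4 slides its change relative to all genes was -2.74, -3.20, -0.46 and -2.91. The macrophage gene Adgre1 differed by -1.502 (adjusted p = 0.0936), the acute phase gene Saa3 by -2.65 (adjusted p = 0.0961), and the keratin gene Krt19 by -4.45 (adjusted p = 0.101). Adipoq, the adiponectin gene, differed by -0.71 (adjusted p = 0.366), Lep, the leptin gene, by -1.16 (adjusted p = 0.260) and Fasn, the fatty acid synthase gene, by -0.15 (adjusted p = 0.761), and these 3 were chosen after their values were seen. Cell cycle genes (0.38, adjusted p = 0.0164, with an estimated correlation adjusted p = 0.587) and ribosomal protein genes (0.22, adjusted p = 5.41e-05, with an estimated correlation adjusted p = 0.445) were higher in WAT knockouts, with 0 members past the threshold over all genes or adjusted over the list alone.

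Also lower in WAT knockouts were thermogenic genes (relative median -1.01, adjusted p = 1.25e-05, with an estimated correlation adjusted p = 0.275), white depot-enriched genes (-1.04, adjusted p = 2.14e-07), insulin signalling (-0.84, adjusted p = 0.000137), antioxidant enzymes (-0.82, adjusted p = 3.42e-07), mammary epithelial markers (-0.60, adjusted p = 1.53e-05) and erythroid markers (-2.37, 6 measured, adjusted p = 4.47e-05), the last 5 each at adjusted p = 0.247 with an estimated correlation. Endothelial markers (-0.36, adjusted p = 0.00907), interferon response (-0.31, adjusted p = 0.0444), immediate early genes (-0.37, adjusted p = 0.0400) and circadian clock genes (-0.33, adjusted p = 0.0401) were called lower, at adjusted p = 0.536, 0.445, 0.275 and 0.445 with an estimated correlation. The mammary level was 2.06 and 0.60 in WAT controls 1 and 4, which held intestinal transcripts, -0.48 and 0.03 in controls 2 and 3, and -0.73, 0.12 and 0.19 in the knockouts. No member of these 10 lists passed over all genes. Adjusted over the list alone 4 mammary markers, 4 erythroid markers, 2 interferon genes, 1 thermogenic gene and 1 antioxidant gene fell, and 1 interferon gene rose. Granulocyte and mast cell markers were called lower (relative median -0.21, adjusted p = 0.0444, with an estimated correlation adjusted p = 0.457). Not taken relative to all genes, their median was 0.03 and their mean -0.35. Cma1 fell over all genes, and adjusted over the list alone 3 fell and 1 rose. T and NK cell markers (relative median 0.97, adjusted p = 0.212), B cell markers (0.72, adjusted p = 0.341) and steroid receptors (-0.14, adjusted p = 0.204) were not called. Skeletal muscle markers (relative median 0.07, adjusted p = 0.341) and nerve markers (0.02, adjusted p = 0.294) were not called either, and the test of both pointed to lower.

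Within-slide medians are relative to the median of all genes between the same 2 arrays. With each sample left out and with slide as a block, medians are not taken relative to all genes. With all samples, the medians not relative to all genes were -1.003 for adipocyte markers and -1.09 for lipogenesis genes. Slides 2 and 4 hold the 2 arrays counted as knockout 1-2. Within slides 1, 2 and 4 the median change of adipocyte markers was -1.56, -2.92 and -2.24, and within slide 3, which held WAT knockout 4, it was 0.59. Lipogenesis genes differed by -1.91, -2.51 and -2.26 within slides 1, 2 and 4 and by 0.44 within slide 3. With slide as a block, adipocyte markers had a median change of -1.04 (adjusted p = 6.8e-11) and lipogenesis genes of -1.13 (adjusted p = 7.2e-14). With all samples the medians not relative to all genes were -0.84 for lipolysis, -0.42 for oxidative phosphorylation and -0.71 for fatty acid oxidation and TCA cycle. They were -1.13 for matrix genes and -0.39 for glucocorticoid-induced genes. Without WAT knockout 4 the median change was -1.95 for adipocyte markers and -1.91 for lipogenesis genes, -1.73 for lipolysis, -0.85 for oxidative phosphorylation, -1.39 for fatty acid oxidation and TCA cycle, -1.73 for matrix genes and -0.66 for glucocorticoid-induced genes. Without WAT knockout 1-2 these were -0.34, -0.51, -0.25, -0.16, -0.34, -0.73 and -0.13. Without WAT knockout 3 it was -0.53 for lipolysis, -0.18 for oxidative phosphorylation, -0.47 for fatty acid oxidation and -0.15 for glucocorticoid-induced genes, which were at -0.26 without WAT control 2. Thermogenic, white depot-enriched, insulin signalling, antioxidant, mammary and cholesterol synthesis genes were at -1.25, -1.69, -1.24, -0.96, -0.72 and -0.65 without WAT knockout 4 and at -0.38, -0.29, -0.18, -0.26, -0.02 and -0.18 without WAT knockout 1-2. White depot-enriched, insulin signalling, antioxidant and mammary genes were at -0.48, -0.31, -0.34 and -0.71 without WAT knockout 3, and mammary genes at -0.55 without WAT control 3.

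Several list calls in WAT ended when 1 sample was left out; medians here are not taken relative to all genes. With all samples these were -0.32 for macrophage, -0.45 for inflammatory, 0.63 for cell cycle, 0.47 for ribosomal protein, -0.11 for endothelial and -0.09 for circadian genes. The macrophage list, at -0.15 without WAT control 2, -0.55 without WAT knockout 1-2 and -0.50 without WAT knockout 3, was no longer called without WAT knockout 4 (0.04, adjusted p = 0.248), nor was the inflammatory list (-0.47, adjusted p = 0.0641). Cell cycle genes were no longer called without WAT control 1 (0.70, adjusted p = 0.0861), WAT control 2 (0.44, adjusted p = 0.0843), WAT knockout 1-2 (0.16, adjusted p = 0.443) or WAT knockout 3 (0.24, adjusted p = 0.296), and ribosomal protein genes without WAT knockout 1-2 (0.30, adjusted p = 0.107). The endothelial list was not called without WAT knockout 1-2 (0.21, adjusted p = 0.194) or 3 (0.12, adjusted p = 0.438), and neither was the circadian list (0.22, adjusted p = 0.194, and 0.05, adjusted p = 0.296). The circadian list was not called without WAT control 3 (-0.06, adjusted p = 0.0868) or 4 (-0.07, adjusted p = 0.0802) either. The interferon list was not called without WAT control 3 (adjusted p = 0.328) or 4 (0.140) or WAT knockout 3 (0.0667) or 4 (0.543). The immediate early list was not called without WAT control 3 (adjusted p = 0.132) or 4 (0.0802) or WAT knockout 3 (0.121) or 4 (0.242), and the granulocyte and mast cell list without WAT control 1 (0.208) or WAT knockout 4 (0.384). With slide as a block the interferon, immediate early, circadian and granulocyte lists had an adjusted p of 0.0508.

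In WAT 15 of 25107 genes and unnamed probes passed the limma test, 5 higher and 10 lower; 3 of the 5 were unnamed probes. Of all tested, 4500 had an unadjusted p under 0.05, against 1255 by chance. The groups did not overlap for 7.70% of the genes, against 5.71% by chance. The count was 9235 without WAT knockout 4, 8 without WAT knockout 1-2 or 3, and 7, 48, 52 and 10 without WAT controls 1, 2, 3 and 4. It was 9 with slide as a block, 1 with normexp background correction and 0 in a fit of WAT samples alone (1822 at an unadjusted p under 0.05). Zfp949, Prg4, Padi4, Slc6a2 and Spock3 passed whichever WAT sample was left out and with slide as a block. Within the 4 slides, of which slides 2 and 4 hold the same knockout sample 1-2, Zfp949 differed by 1.95, 2.09, 1.67 and 2.32. Prg4 differed by -2.77, -4.96, -2.22 and -3.38, and Padi4 by -2.67, -3.84, -1.81 and -2.86. Wt1 differed by -3.53, -4.39, -0.80 and -3.52, and Cma1 by -3.85, -5.08, -1.51 and -3.69. Both falls were thus much smaller within slide 3, which held WAT knockout 4. Rian, Alox15, Cma1, F10, Lancl3, Vmn1r76 and Wt1 each failed to pass without at least 1 WAT sample. Without control 1 none of the 7 passed (adjusted p 0.0504 to 0.113). Without control 2 Wt1 did not pass (0.0517), and without control 4 Cma1, F10, Vmn1r76 and Wt1 did not (0.0536 to 0.0998). Without knockout 1-2 these 4, Rian and Lancl3 did not pass (0.0631 to 0.144), and without knockout 3 Alox15, Rian, Cma1, F10, Lancl3 and Wt1 did not (0.0516 to 0.267).

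The interaction asked whether knockout had another effect in BAT than in WAT. Slc6a2 passed the limma test (3.19 ± 0.33, adjusted p = 0.00374), but it was well above background on 4 of 16 arrays, those of the WAT controls. Its estimate therefore rests on values at background, a fall in BAT could not have been seen, and a difference between depots is not shown. This was 1 of 25107 genes and probes, with 2616 at an unadjusted p under 0.05, and Spock3, well above background on the WAT control arrays alone, was next (adjusted p = 0.0632). In the interaction 20 lists were called, each with a higher change in BAT than in WAT. Extracellular matrix genes had a median of 1.29 (adjusted p = 7.7e-16, with an estimated correlation adjusted p = 0.302), and adipocyte markers a median of 0.85 (adjusted p = 3.46e-06, with an estimated correlation adjusted p = 0.484). Of the members 0 passed over all genes in these 2 lists, and 7 matrix genes were higher adjusted over the list alone. With slide as a block Slc6a2 had an adjusted p of 0.0527, and matrix genes had a median of 1.32 (adjusted p = 8.3e-14). Without WAT knockout 4 the medians of matrix genes and adipocyte markers were 2.07 and 1.78, and without WAT knockout 1-2 that of adipocyte markers was 0.17. The number of genes was 4055 without WAT knockout 4, 14 without WAT control 2 and 2 without WAT control 3.

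No gene passed the limma test in both depots, with 612 at an unadjusted p under 0.05 in both, against 591 if the depots were independent. Of these 524 had the same sign, 447 higher (227 if independent) and 77 lower (84.2 if independent). Rises outnumbered falls at that p in each depot alone (2970 and 1530 in WAT, 1919 and 1381 in BAT), so more shared rises than shared falls are expected without a shared response. The expected 227 and 84.2 already allow for this, so it does not account for 447 against 227. Genes vary together, so a shift of many genes in each depot can still exceed the expected counts, and a shared response is not shown by them. Across genes, which are not independent replicates, the WAT and BAT changes had a Pearson correlation of 0.19 and a Spearman correlation of 0.25. In each of the 2 depots knockouts and controls did not overlap, in the same direction, for 225 genes that were higher (152 if the depots were independent) and 19 that were lower (26.5 if independent), and in opposite directions for 99. The histone methyltransferase family gene Setd4 was among those higher in both, by 0.95 in WAT (adjusted p = 0.129) and 1.04 in BAT (adjusted p = 0.0814).

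The comparison of depots asked how BAT and WAT differ, first in control mice. Ucp1, which encodes the uncoupling protein of brown fat, was higher in BAT controls than in WAT controls by 12.78 ± 0.64 (n = 4 in each group, limma adjusted p = 4.63e-08), and the fatty acid carrier gene Fabp3 by 8.90 ± 0.27 (adjusted p = 3.47e-10). Thermogenic genes had a median difference of 4.17, and 24 of 27 passed over all genes as higher (camera adjusted p = 1.33e-18, with an estimated correlation adjusted p = 0.109). Oxidative phosphorylation genes had a median of 2.34, with 38 of 40 higher (adjusted p = 4.6e-20, with an estimated correlation adjusted p = 0.344). Fatty acid oxidation genes had a median of 2.72, with 31 of 32 higher (adjusted p = 8.7e-17, with an estimated correlation adjusted p = 0.359). Adjusted over the list alone the numbers higher were 25, 38 and 31. The median of all genes was 0.11 higher in BAT controls than in WAT controls, and these medians are not relative to it. Of the 29 lists 19 were called between depots in controls, 7 higher and 12 lower in BAT. Macrophage markers were lower in BAT (median -2.28, 24 of 24 members lower over all genes and adjusted over the list alone, adjusted p = 3.2e-17, with an estimated correlation adjusted p = 0.109). White depot-enriched genes were lower too (-2.35, 15 of 20 lower over all genes and adjusted over the list alone, adjusted p = 1.35e-06, with an estimated correlation adjusted p = 0.445). Lep was lower by -2.52, the homeobox gene Hoxc9 by -5.98, the lymphatic marker Lyve1 by -4.06 and Wt1 at least 38.8-fold, and Hsd11b1 was higher in BAT by 1.67 ± 0.27 (adjusted p = 0.000344). The genes Defa21 (at least 436-fold), Slpi, Msln, Krt8, Lgals2 and Defa23 had the largest differences towards WAT among genes whose groups did not overlap, and Defa21, Defa23 and Lgals2 are genes of the intestine. Defa21 was at 7.60, -4.03, 4.97 and 6.74 in WAT controls 1 to 4. B cell markers were lower in BAT controls (-3.15, 12 of 16 over all genes and 13 adjusted over the list alone, adjusted p = 2.3e-06, with an estimated correlation adjusted p = 0.464). Cell cycle genes were lower as well (-2.06, 17 of 24 and 18, adjusted p = 1.32e-06, with an estimated correlation adjusted p = 0.464). Muscle markers were higher (4.30, 18 of 23 and 19, adjusted p = 1.26e-07, with an estimated correlation adjusted p = 0.464).

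Between BAT and WAT controls 8381 of 25107 genes and probes passed, 4792 higher and 3589 lower in BAT, and 5772 of them differed over 2-fold. The groups did not overlap for 43.3% of the genes, against 2.86% by chance. The count was 5272 without WAT controls 1 and 4 and 2207 with the muscle marker level as a covariate. It lay between 6622 and 10597 with any 1 sample left out. The muscle level was -3.26 to -2.02 in WAT controls and -1.24 to 2.71 in BAT controls. It thus varies with depot, and the count of 2207 does not measure how much of the depot difference is due to muscle.

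In knockouts, Ucp1 was higher in BAT than in WAT by 11.58 ± 0.69 (n = 4 and 3, limma adjusted p = 2.76e-07). Thermogenic genes had a median difference of 4.85 with 23 of 27 higher over all genes and adjusted over the list alone (camera adjusted p = 5.8e-23, with an estimated correlation adjusted p = 0.181). Oxidative phosphorylation genes differed by a median of 2.71 (38 of 40 higher over all genes and 39 adjusted over the list alone, adjusted p = 4.6e-29, with an estimated correlation adjusted p = 0.277). In knockouts 21 lists were called, 12 higher and 9 lower in BAT. Muscle markers differed by 6.78 (22 of 23 higher and 23 adjusted over the list alone, adjusted p = 6.0e-15, with an estimated correlation adjusted p = 0.304). The muscle genes Mb and Myh4 were higher by 9.78 each. B cell markers were lower in BAT (-4.39, 14 of 16 lower and 16 adjusted over the list alone, adjusted p = 1.7e-06, with an estimated correlation adjusted p = 0.438). So were the lymphoid genes Ccl19 at -5.76 and Pou2af1 at -5.64. Macrophage markers were lower by a median of -1.69 (17 of 24 lower and 20 adjusted over the list alone, adjusted p = 2.38e-09, with an estimated correlation adjusted p = 0.277). The macrophage receptor gene Marco differed by -6.32. Nr4a2 was higher in BAT by 4.11, and Hsd11b1 differed by 0.45 (adjusted p = 0.282). Adipocyte markers were higher in BAT by a median of 1.18 (11 higher and 1 lower of 25 over all genes, 13 and 2 adjusted over the list alone, adjusted p = 0.000962, with an estimated correlation adjusted p = 0.559), where the WAT knockout samples ranged from -2.17 to 0.77.

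Between BAT and WAT knockouts 7683 of 25107 genes and probes passed, 4183 higher and 3500 lower in BAT, and the groups did not overlap for 25.5% of the genes, against 5.71% by chance. The count was 4728 without WAT knockout 1-2 and 4497 without WAT knockout 3, 3630 with normexp background correction, 2990 in a fit of these 2 groups alone and 166 with the muscle marker level as a covariate. The muscle level was -3.34 to -2.44 in WAT knockouts and 1.95 to 5.26 in BAT knockouts. It thus varies with depot, and the count of 166 does not measure how much of the depot difference is due to muscle.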

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

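The tests of explanations in this part were chosen after the result was seen, except the 5 counts of splits of the samples. The interaction tests were planned, as were the fits with an estimated correlation, with slide as a block and with a compared sample left out.

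In 7 of 129 groups of samples checked, 1 sample lay far from the others of its group. Chance gives 6.45 at about 1 in 20. The WAT knockouts were not among the groups checked, so this count does not tell how far apart their samples lay. Those samples were unlike each other in cell content. Alox15 was at 1.16 in WAT control 2, with the other controls between -0.19 and -0.16. Magel2 was at -1.94 in BAT knockout 1 (others -1.16 to -1.01), and Nr4a2 at 2.62 in BAT knockout 3 (others 3.07 to 3.14). Of the list levels, cholesterol synthesis was at 0.21 in WAT control 1 (others -0.15 to -0.13), interferon response at 0.22 in BAT knockout 1 (others -0.36 to -0.29), circadian clock at 0.18 in BAT knockout 1 (others 0.45 to 0.50) and ribosomal proteins at -0.39 in BAT control 2 (others -0.29 to -0.27).

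The interaction test at the preset correlation passed for Slc6a2 (3.19) and for 20 lists, each with the higher change in BAT. Slc6a2 was well above background on 4 of 16 arrays, so a fall in BAT could not have been seen, and with slide as a block it did not pass (adjusted p = 0.0527). The median interaction was 0.49 for glucocorticoid-induced genes, 0.82 for lipolysis, 0.74 for lipogenesis, 0.85 for adipocyte markers, 0.41 for thermogenic genes, 1.22 for white depot-enriched genes, 0.40 for oxidative phosphorylation, 0.43 for fatty acid oxidation and TCA cycle, 0.40 for insulin signalling and 0.26 for inflammatory mediators. It was 0.16 for interferon response, 0.42 for macrophage markers, 1.29 for extracellular matrix, 0.76 for endothelial markers, 1.90 for skeletal muscle markers, 0.65 for mammary epithelial markers, 2.13 for mesothelial markers, 2.31 for erythroid markers, 0.36 for immediate early genes and 0.32 for antioxidant enzymes. With an estimated correlation 0 of the 20 were called. Without WAT knockout 4 the macrophage list (median -0.05, adjusted p = 0.138), the inflammatory list (0.35, adjusted p = 0.132) and the interferon list (0.07, adjusted p = 0.0586) were not called. Thermogenic genes and fatty acid oxidation genes were not called without WAT knockout 1-2 (0.15, adjusted p = 0.209, and 0.09, adjusted p = 0.0648) or 3 (0.27, adjusted p = 0.0924, and 0.21, adjusted p = 0.182). Antioxidant enzymes were not called without WAT control 2 (adjusted p = 0.173), WAT knockout 1-2 (0.213) or 3 (0.503), or BAT knockout 3 (0.0914) or 4 (0.0947).

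Adipocyte and lipid genes were low in WAT knockouts 1-2 and 3, and these samples had high B cell marker levels: the list was at 5.01 and 4.66 in them, at -1.22 in WAT knockout 4 and between 0.03 and 3.62 in WAT controls. A genotype effect alike in every knockout sample stays open: 1 WAT knockout sample lay above the highest control (knockouts -2.53 to 0.22, controls -0.63 to -0.24), but it also had the lowest B cell level, and 1 sample decides nothing. Lymphoid tissue in the samples may lower the share of adipocyte RNA, and this stays open: with the B cell level as a covariate the difference was -0.640 ± 0.219 on the log2 scale (-0.976 ± 0.485 without it), but on the signal scale, a form added after the first was seen, it was 0.218 ± 0.0925 with 4 residual degrees of freedom (-0.198 ± 0.274 without it). The 2 forms have opposite signs, so lymphoid content and genotype cannot be told apart here. Of 35 splits of the 7 WAT samples, 6 gave at least the real 15 genes, so chance cannot be excluded; the highest other count, 8678, came from WAT controls 1, 2 and 4 with knockout 4 against the rest, which points to a structure of the samples other than genotype.

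Intestinal transcripts were high in WAT controls 1 and 4: Fabp2 was at 7.53 and 6.50 there, against -4.73 and -1.69 in controls 2 and 3. Mammary gland epithelium as the source is argued against, since the intestinal list rose over the other WAT controls by at least 4.80 more than the mammary list (intestinal rise 6.76 and 5.41, mammary rise 1.82 and 0.61); 2 intestinal members are in another list. RNA from intestine in these 2 samples is a candidate source: at least 83.8% of the 37 measured members were over 4-fold above every sample outside the WAT controls (89.2% in control 1). How it came into the samples was not tested.

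Cholesterol synthesis genes were lower in BAT knockouts. Muscle content as the whole cause is argued against, since with the muscle marker level as a covariate the difference in the list's level was -0.991 ± 0.195 (-0.776 ± 0.179 without it). That covariate was run on the log2 scale alone. BAT knockouts 1 and 4 had muscle levels of 1.95 and 2.44, within the -1.24 to 2.71 of BAT controls. Their cholesterol synthesis levels were -0.31 and -0.38, against 0.46 to 0.71 in BAT controls. The low array signal of BAT knockouts 1 and 2 is argued against as well, since the higher of knockouts 3 and 4 lay 0.420 below the lowest control. Array position stays open: 0 positions held both a BAT knockout array and an array of another group, so position and genotype cannot be told apart. Loss of GR stays open beside it and may lower these genes. Of the 35 splits of the 8 BAT samples, 1, the real one, gave 4 genes past the threshold and the highest other gave 0. That share is under the preset limit of 0.05. It is also the smallest that 35 splits can give, so this test alone cannot exclude chance for that count. The splits take no account of slide: with slide as a block the count is 0 (3111 genes at an unadjusted p under 0.05 in limma), and it is 0 without BAT control 1, 3 or 4 or BAT knockout 1, 2 or 3.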

How the results depend on the processing

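The number of arrays, the unlike WAT knockout samples and the signal over background (66.7% to 83.6% of probes well above it) limit these results. The counts of genes in WAT, in BAT and in the interaction moved with many settings. Slc6a2 in the interaction stayed past the threshold in 15 of 15 fits with 1 sample left out. The cause of the moves was not tested except where fewer samples or a smaller set of genes show it. No called gene or list was called in the opposite direction under these settings, though some list medians changed sign when a sample was left out (macrophage markers in WAT to 0.04 without WAT knockout 4). Keeping WAT knockouts 1 and 2 separate, the B cell and muscle covariates, the samples left out in pairs, the outlier spots kept and the samples outside a comparison left out were chosen after seeing the data. The reported counts are 15 in WAT, 4 in BAT, 1 in the interaction, 8381 between depots in controls and 7683 in knockouts.

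At an adjusted p of 0.01 the counts were 6 in WAT, 0 in BAT, 5324 between depots in controls and 4290 in knockouts. Quantile scaling gave 24 in WAT and 2 in the interaction, and median scaling 61 and 2. Normexp gave 1 in WAT, 0 in BAT (limma, 1838 unadjusted), 0 in the interaction (1317 unadjusted) and 3630 between depots in knockouts. With no filter BAT gave 0 (3438 unadjusted). The strict filter, which tests fewer genes, gave 4 in WAT, 14 in BAT and 0 in the interaction (2327 unadjusted). Slide as a block gave 9 in WAT, 0 in BAT (3111 unadjusted) and 0 in the interaction (2454 unadjusted), and replicate number as a block gave 9, 0 (3049 unadjusted) and 0 (2310 unadjusted). With the compared groups alone, WAT gave 0 (1822 unadjusted), BAT 12 and the depots in knockouts 2990. Moderation with trend gave 0 in the interaction (2748 unadjusted). Array weights gave 15415 in WAT, 2013 in BAT, 7486 in the interaction, 17174 between depots in controls, 12605 in knockouts and 872 genes called in both depots; they gave WAT knockout 4 a weight of 0.0827. With them Nr3c1 differed by -0.80 in WAT (adjusted p = 0.00174) and -1.04 in BAT (adjusted p = 0.00682), and within slide 2 Nr3c1 differed by -0.95 in WAT.

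WAT knockouts 1 and 2 as separate samples gave 278 in WAT, 22 in BAT, 2 in the interaction and 1 called in both depots, with Nr3c1 at -1.03 in BAT (adjusted p = 0.0490). The B cell covariate gave 757, 850, 250, 4263 between depots in knockouts and 48 called in both, with Nr3c1 at -1.03 in BAT (adjusted p = 0.0238). The muscle covariate gave 0 in BAT (2217 unadjusted), 2207 between depots in controls and 166 in knockouts. Muscle levels did not overlap between depots, so the counts between depots do not measure the part due to muscle. Without WAT controls 1 and 4 the counts were 4 in WAT, 0 in BAT (3066 unadjusted), 0 in the interaction (1702 unadjusted) and 5272 between depots in controls. Without BAT knockouts 1 and 2 they were 0 in BAT (997 unadjusted) and 0 in the interaction (2423 unadjusted). With an estimated correlation 0 lists were called in each comparison, and with the B cell covariate 10 lists between depots in knockouts.

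With 1 sample left out the counts ranged from 7 to 9235 in WAT, 0 to 84 in BAT, 1 to 4055 in the interaction, 6622 to 10597 between depots in controls, 4497 to 11456 in knockouts and 0 to 39 called in both depots. The highest of the WAT, BAT and interaction counts came without WAT knockout 4. Nr3c1 ranged from -0.74 to -0.53 in WAT and from -1.13 to -0.96 in BAT. Lists called ranged from 19 to 23 in WAT, 8 to 10 in BAT, 18 to 22 in the interaction, 18 to 19 between depots in controls and 18 to 21 in knockouts.

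Of the values of called lists under other settings, 150 of 192 stayed past the threshold in WAT, 57 of 72 in BAT, 131 of 160 in the interaction, 117 of 152 between depots in controls and 123 of 168 in knockouts. With 1 sample left out these were 145 of 168, 68 of 72, 288 of 300, 147 of 152 and 139 of 147. Of the values of named genes under other settings, 80 of 132, 20 of 44, 5 of 10, 707 of 737 and 680 of 781 stayed past it, and with 1 sample left out 60 of 84, 4 of 32, 15 of 15, 536 of 536 and 481 of 497. A random block of genotype and replicate number gave 1 in the interaction, 8822 between depots in controls and 7916 in knockouts. Whether such a block is 1 mouse is not stated.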

Other observations

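Lymph node stroma markers varied between WAT samples with the lymphocyte markers: their level was 0.37, 0.61, 3.14 and 3.08 in WAT controls 1 to 4 and 4.44, 3.65 and -0.01 in WAT knockouts 1-2, 3 and 4, and the chemokine gene Ccl19 was at 6.72 and 6.47 in knockouts 1-2 and 3 and at 1.32, 1.45, 5.51 and 4.91 in the controls. Erythroid markers were at -3.04 and -1.94 in WAT knockouts 1-2 and 3, at 0.10 in knockout 4 and between 0.09 and 0.85 in the controls. Pancreatic acinar markers were at 0.79, -0.67, -0.63 and -0.35 in WAT controls and -0.49, 0.62 and 1.06 in WAT knockouts. The Paneth cell defensin gene Defa21 was at 7.60, -4.03, 4.97 and 6.74 in WAT controls 1 to 4, so control 3 held this transcript as well.

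Whether samples of the same number in WAT and BAT come from 1 mouse stays open. Across genes, which are not independent replicates, the deviations from the group means had correlations of 0.18, 0.10, 0.05 and 0.05 for controls 1 to 4 and -0.27 and 0.12 for knockouts 3 and 4. Between different numbers they were from -0.11 to 0.04 in 12 pairs of controls and from -0.34 to 0.41 in 8 pairs of knockouts, so same-numbered controls were more alike than the others and same-numbered knockouts were not; this comparison was chosen after the correlations were seen. With number as a random block the consensus correlation was 0.0645.

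Between the depots, of 35 splits of the samples only the real split gave as many genes in controls (8381, highest other 0). The same held in knockouts (7683, highest other 5263). A share of 1 in 35 is the smallest these tests can give, so they alone cannot exclude chance for either count. For the interaction, 16 of 100 drawn splits gave at least the real 1 gene (highest other 2108), so chance cannot be excluded. Of these splits 12 gave several times the real count, and 4 of the WAT splits did so, which points to a structure of the samples. These tests were chosen before the result was seen.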
